A study of Mus musculus with 8 samples.

How the data were processed

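The series holds RNA-seq of mouse small cell lung cancer (SCLC) cell lines, grown from primary lung tumors that carried a Mycl transgene and had lost Rb1, per the labels. Each of 4 cultures was profiled after transfer of an empty vector and after overexpression of mouse Nfib, a transcription factor of the nuclear factor I family, which gives 4 empty vector and 4 Nfib libraries. Group and replicate number came from the sample titles and sources. The sample descriptions name the line of each pair, Lmyc1 for replicate 1, Lmyc3 for replicates 2 and 3, and Lmyc5 for replicate 4. They also call replicates 1 and 2 old and replicates 3 and 4 new, words that no source used here explains. The titles use the word Tumor for the Nfib arm, and the source field, which states the vector, was followed. Nothing says whether the 2 arms of a pair were grown or sequenced more than once, so p-values measure the spread between these samples.

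The authors deposited a table of read counts per Ensembl gene, whole numbers that were not normalized, with gene symbols, biotypes and coordinates. Libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. TopHat2 2.1, Bowtie 1.0.0, SAMtools 0.1.19 and DESeq2 are named, with the mouse build GRCm38 (mm10), per the submitters' processing notes. The counting program, its strand setting and the annotation release are not given in the sources used here. Overlapping and antisense genes therefore cannot be told apart, and genes with near-identical copies, such as those of ribosomal proteins, are uncertain. Of the 22691 identifiers, 22423 were found in a GRCm38 reference annotation and 22368 of these lay on the same chromosome within 100 kb. Every gene of the table had at least 1 count over the 8 libraries. Coordinates are those of the table.

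Counts per library summed to between 21815264 and 29934021, and 3 counts, the upper limit that a count of 0 allows, corresponded to between 0.100 and 0.138 CPM (counts-per-million). Such limits cover counting error only, since the reads carry no molecular identifiers.

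The test fixed before the data were examined was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, original form of the fit) of Nfib against empty vector without a block. It used TMM factors, edgeR's expression filter by group (13380 genes kept) and Benjamini-Hochberg adjustment at 0.05. The replicate number as a block was the paired form of the same test. The pairing comes from the labels, which give both libraries of a number the same cell line. It was checked by correlating each library's deviations from its group's mean across genes: libraries of the same number gave r of 0.908, 0.884, 0.935 and 0.929, and no other combination exceeded 0.0647. Alternatives fixed at the same time were DESeq2 1.42.0 with and without the block, limma 3.58.1 (voom) with the block, the line as a block, the Lmyc3 pairs summed per arm, the pair as a random effect, old or new as a covariate, DESeq2 size factors, total counts, other low-count filters, other thresholds, Nfib left out, and each replicate or library left out. An interaction of Nfib with old or new was tested by edgeR with the block.

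Because the edgeR test called no gene with or without the block, genes and lists are described with DESeq2's Wald test with the replicate block, one of the alternatives fixed beforehand. Its use for naming genes was chosen after the values were seen. In the text, rose and fell mean that a gene passed this paired DESeq2 test at an adjusted p under 0.05. DESeq2 fold changes are not shrunk. Adjusted p-values that it left undefined (260 genes) were kept so. A gene without an adjusted p counts as not passing, also in the fits that leave out a pair. CPM values use TMM-scaled library sizes, except for the limits above and the values of Xist and Y-linked genes, which use total counts, and within-pair log2 ratios use log2 CPM with a prior count of 2.

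Named genes followed a rule fixed before the data were examined. It asked for Nfib, the other nuclear factor I genes, Mycl and Rb1 in every library, and for the genes of largest change each way (15 with the block) among those passing with a mean of at least 1 CPM and the same sign in all 4 pairs. It also took members of fixed lists that pass, interaction genes that pass, and the members of highest mean CPM of the lists for other cell types. The parts that need an edgeR call named no gene, and the same rule was applied to the paired DESeq2 test. Some genes that the rule names, and the results of 2 lists, are not reported here, while counts over all genes or lists include them. The 29 lists of genes, also fixed beforehand, were tested with camera (preset correlation of 0.01, without and with the block) and with fry, for the 28 lists with at least 3 tested members.

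The edgeR test without and with the block and DESeq2 with the block were tested on simulated counts modelled on the 8 libraries. There 13251 genes were fitted, and 200 genes were changed within pairs. Other tests were not simulated. At 1.5-fold, 2-fold and 4-fold, edgeR without the block recovered 0%, 7.46% and 43.9% of changed genes, with no false call among 34. With the block it recovered 44.8%, 71.6% and 92.4%, and 9.74% of 154 calls were false. DESeq2 with the block recovered 64.2%, 85.1% and 90.9%, and 23.4% of 209 calls were false, above the 0.05 aimed for. These shares hold for 200 changed genes. On the real libraries edgeR with the block called 0 genes, so the simulated counts do not match them in full. Figures were drawn with matplotlib.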

Results

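Gene expression was measured by RNA-seq in cell lines grown from primary mouse SCLC, a neuroendocrine lung tumor, with and without forced expression of Nfib. The tumors carried a Mycl transgene and lacked Rb1, per the labels. The data comprised 4 empty vector libraries and 4 Nfib libraries, paired by cell line. Read counts per library ranged from 21815264 (empty vector replicate 2) to 29934021 (empty vector replicate 1), and between 17530 and 18227 genes had at least 1 count in a library. Pairs 2 and 4 had the deeper library in the Nfib arm, and pairs 1 and 3 in the empty vector arm. The most abundant gene was mt-Co1 in all 8 libraries, at between 0.712% and 1.39% of counts.

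The targeted gene was examined first. Nfib (ENSMUSG00000008575, chromosome 4, 82290173 to 82705750, GRCm38) was higher in the Nfib library of each pair. It rose from 72.0 to 1282 CPM in replicate 1 and from 400.2 to 4682 CPM in replicate 2. In replicate 3 it rose from 163 to 2933 CPM, and in replicate 4 from 487 to 3590 CPM. The group means were 281 ± 195 CPM (SD, n = 4) with empty vector and 3122 ± 1423 CPM (SD, n = 4) with Nfib. The lowest Nfib library lay above the highest empty vector library. The paired log2 fold change was 3.68 ± 0.21 (SE), with a Benjamini-Hochberg adjusted p of 1.76e-64 in the DESeq2 test. The paired edgeR test gave 3.69 ± 0.25 with an adjusted p of 0.0657, and without the block edgeR gave an unadjusted p of 0.00103. EdgeR reports no SE, so the value after ± is the log2 fold change divided by the square root of the test's F. Counts per gene do not separate endogenous Nfib from the introduced copy.

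**Figure D1:**
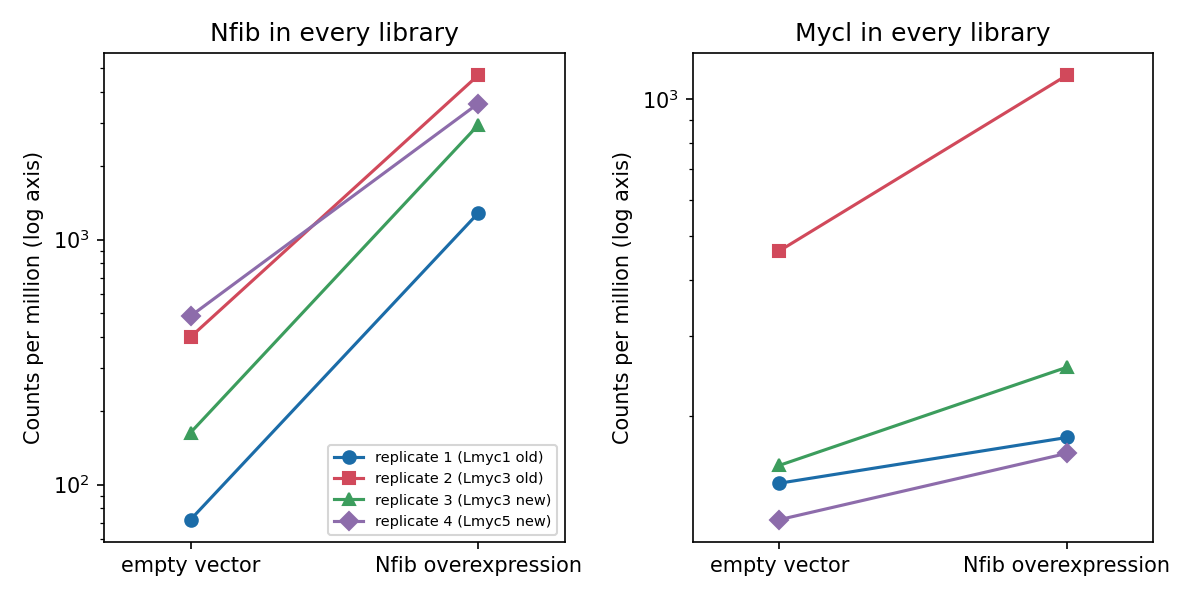
Nfib (left) and Mycl (right) in every library, in CPM on a log axis, with a line joining the empty vector and Nfib libraries of each replicate number. Nfib libraries lie between 1282 and 4682 CPM for Nfib and empty vector libraries between 72.0 and 487 CPM, and Mycl is highest in both libraries of replicate 2.

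Mycl, the oncogene of the tumor model, rose with Nfib in all 4 pairs, by 0.70 ± 0.16 on the log2 scale (SE, DESeq2 Benjamini-Hochberg adjusted p of 0.00148). The rise ranged from 0.33 in pair 1 to 1.29 in pair 2, where Mycl went from 463 to 1128 CPM. Whether the endogenous gene or the Mycl transgene rose cannot be told from counts per gene. The other members of the Nfib family did not pass. Nfic was higher in all 4 pairs (0.25 ± 0.10, adjusted p of 0.158), Nfix ranged from -0.50 in pair 3 to 2.75 in pair 2, and Nfia had a log2 fold change of -0.22 ± 0.21, which was 0.0043 without replicate 2. Rb1 (30.4 ± 13.02 against 26.0 ± 10.9 CPM, SD, n = 4) did not pass either. Counts per gene do not show whether a deleted exon was missing. The paired DESeq2 and edgeR tests, adjusted over the list alone, each called 2 of the 4 family genes, Nfib among them, both higher.

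The central comparison asked which genes change when Nfib is forced up in these lines. The largest rises were in genes with few counts in the empty vector libraries and of varied function, among them Tmem132b, the choline dehydrogenase Chdh, the secreted chaperone Clu, the integrin Itga1, the sodium/hydrogen exchanger Slc9a2, the potassium channel Kcnq3 and the water channel Aqp5. The genes with the largest falls included Ocm, the collagen Col6a5, the coagulation factor F5, the sialyltransferase St6galnac5, the mechanosensitive channel Piezo2 and the transcription factor Sall4. Among more abundant genes near to a call in the paired edgeR test, the glutamate receptor gene Gria2 fell by 0.60 in log2 terms and the vesicular monoamine transporter Slc18a1 by 1.19, whereas the convertase Pcsk6 rose by 1.96, Trim67 by 0.60 and the glycosyltransferase Mgat4b by 0.76.

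The edgeR test without the block, the one fixed as primary, called 0 genes higher and 0 lower of 13380. At an unadjusted p under 0.05 it had 83 genes, where 669 would arise by chance. With the replicate block edgeR also called 0 genes at 0.05, with 2012 genes at an unadjusted p under 0.05, a smallest adjusted p of 0.0657, and 15 genes (11 higher, 4 lower) at an adjusted p under 0.1. DESeq2 called 3 genes higher and 0 lower without the block, and limma voom with the block called 3 higher and 0 lower. DESeq2 with the replicate block called 543 genes, 249 higher and 294 lower. Scaling by total counts in that test gave 324 higher and 201 lower, of which 450 genes were shared with the 543 in direction. In edgeR's bias-adjusted form of the fit, added after the values were seen, the block gave 30 higher and 14 lower genes, and 42 of these 44 were also called by the paired DESeq2 test.

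Of the 543 genes, 542 had an unadjusted p under 0.05 in the paired edgeR test and 521 moved the same way in all 4 pairs (236 up, 285 down). Over all genes tested, 25.6% had the same sign in all 4 pairs, against 12.5% by chance. The rises were larger, with a median log2 fold change of 0.93 among higher genes and -0.50 among lower genes, and more than 2-fold changes in 116 higher and 51 lower genes. Calls depended on each pair: 103 of the 543 genes (58 higher, 45 lower) passed in each of the 4 fits that left out 1 pair. Without replicate 3 the test called 143 higher and 89 lower genes, without replicate 4 it called 108 and 145, and without replicate 1 it called 179 lower genes.

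Tmem132b rose from 0.208 ± 0.241 to 9.61 ± 10.2 CPM (SD, n = 4), with a paired log2 fold change of 5.66 ± 0.63 (SE, DESeq2 adjusted p of 8.75e-16). Clu rose from 0.695 ± 0.748 to 5.67 ± 5.20 CPM, by 3.22 ± 0.48 (adjusted p of 2.88e-08). Kcnq3 rose from 1.14 ± 1.13 to 7.58 ± 5.35 CPM, by 3.03 ± 0.52 (adjusted p of 2.15e-06). These genes and Itga1 (3.52 ± 0.75) passed without any single pair. Chdh (4.01 ± 0.67), Slc9a2 (3.63 ± 0.67), Aqp5 (3.08 ± 0.71), Synm (3.04 ± 0.74) and Podn (2.997 ± 0.80) passed in 3 of the 4 fits that left out a pair, and Adcyap1r1 in 2. A530053G22Rik, Lgi3, Pm20d2 and Adamts9 passed in 1. Without replicate 2, DESeq2 gave no adjusted p for Chdh, Slc9a2, A530053G22Rik and Pm20d2, which is counted here as not passing. Several of these genes had a count of 0 in an empty vector library, and their fitted fold changes are imprecise.

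Among falling genes, Piezo2 went from 14.2 ± 3.82 to 4.65 ± 3.31 CPM (SD, n = 4), with a paired log2 fold change of -1.89 ± 0.36 (SE, DESeq2 adjusted p of 3.91e-05). Fam19a4 (-1.74 ± 0.37), Upp1 (-1.78 ± 0.39) and St6galnac5 (-2.13 ± 0.45) also passed without any single pair. Col6a5 (-2.33 ± 0.46), Smyd1 (-1.71 ± 0.35) and Kl (-1.66 ± 0.44) passed in 3 of 4 such fits. Ocm (-2.99 ± 0.72), F5 (-2.20 ± 0.57), Pgr15l, Sall4 and Shisa3 passed in 2, Mettl11b and Stra6 in 1, and Ppp1r17 in 0. For Ocm and Ppp1r17 DESeq2 gave no adjusted p without replicate 2. The 15 genes nearest to a call in the paired edgeR test were Tmem132b, Nfib, Chdh, Gria2, Trim67, Mgat4b, Slc18a1, Clu, Pcsk6, Slc1a2, Myl4, Vasn, Kcnd3, Nebl and Renbp. Gria2 was their most even member, with within-pair log2 ratios between -0.65 and -0.52 and a mean of 188 ± 82.4 CPM in empty vector against 125 ± 56.2 CPM in Nfib libraries (SD, n = 4).

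**Figure D2:**
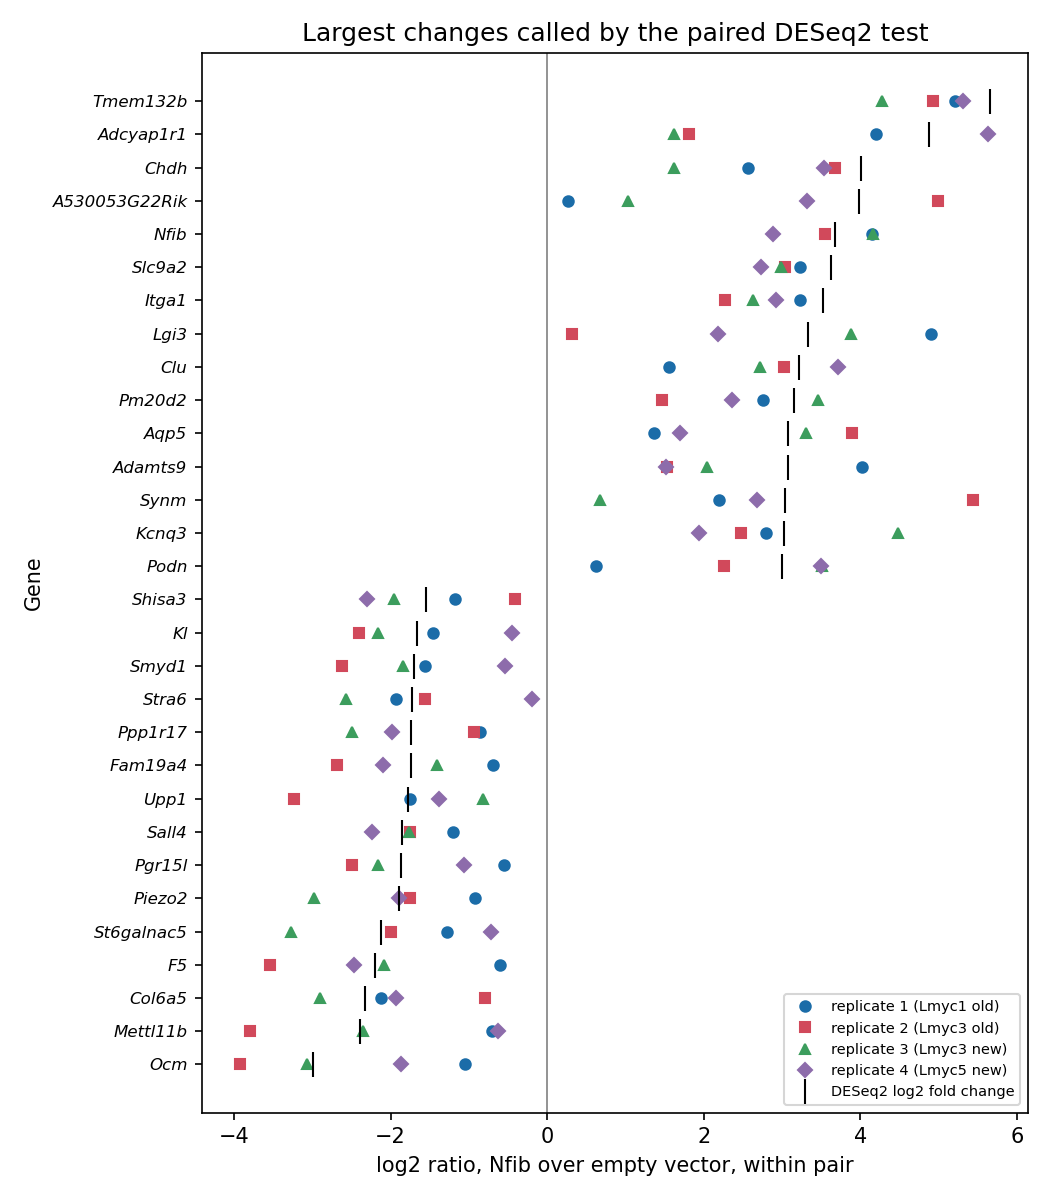
Within-pair log2 ratios (Nfib over empty vector, log2 CPM with a prior count of 2) of the 15 genes with the largest rise and the 15 with the largest fall in the paired DESeq2 test, among genes with the same sign in all 4 pairs. Each symbol is a pair and the black tick is the DESeq2 log2 fold change, which lies outside the symbols for some genes with very low counts.

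Some neuroendocrine and neuronal genes fell with Nfib. As lists, both passed camera with the preset correlation and the block (adjusted p of 7.81e-06 and 0.00219). Neither passed camera with an estimated correlation and the block (adjusted p of 0.532 for both) or fry with the block (0.191 and 0.164). Of 31 tested neuroendocrine markers, 7 fell and 0 rose: the granin Scg2, Resp18, Snap25, the lung lineage factor Nkx2-1, Prox1, Eno2 and Syt1. Of 50 tested neuronal and synaptic genes, 7 fell and 0 rose: Gria2, Rab3a, Nefh, Sncb, Celf4, Shank1 and Dlg4. The class markers Insm1, Chga and Uchl1 did not pass. On the opposite side, the Notch pathway genes Notch2 and Hey1 rose, 2 of 16 tested members of a list of Notch and non-neuroendocrine markers, with 0 falling.

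Scg2 fell by 1.23 ± 0.23 in log2 terms (SE, DESeq2 Benjamini-Hochberg adjusted p of 2.32e-05), in all 4 pairs and most in pair 3, from 238 to 63.3 CPM. Resp18 dropped by 1.17 ± 0.27 (adjusted p of 0.00102) and Nkx2-1 by 0.39 ± 0.11 (adjusted p of 0.0122), from 183 ± 24.6 to 142 ± 28.8 CPM (SD, n = 4). Chga had a log2 fold change of 0.02 ± 0.40. Adjusted over the list alone, 11 neuroendocrine markers fell in the DESeq2 test and 6 in the paired edgeR test, which called 0 of them over all genes. Scg2 and Resp18 passed in 3 of the 4 fits that left out a pair, Nkx2-1 and Syt1 in 2, and Snap25, Prox1 and Eno2 in 1. The count of 7 became 3 without replicate 2 and 5 with total-count scaling. For the neuronal list the counts adjusted over the list alone were 10 and 6. Of its genes, Gria2, Rab3a and Sncb passed in all 4 such fits, Nefh in 3, Shank1 in 1 and Celf4 and Dlg4 in 0, and with total-count scaling 5 fell. The median within-pair log2 ratio of the neuroendocrine list was negative in every pair, at -0.08, -0.38, -0.35 and -0.28, and that of the neuronal list at -0.11, -0.29, -0.17 and -0.11. In the Notch list 2 genes rose in DESeq2 and 1 in edgeR when adjusted over the list alone. Notch2 rose by 1.33 ± 0.30 and Hey1 by 0.85 ± 0.22 (SE), and they passed in 2 and 1 of the 4 fits that left out a pair. Notch2 had at most 0.57 CPM in the libraries of pairs 1 and 3, so its rise rests largely on pairs 2 and 4. Hey1 had a log2 ratio of only 0.12 in pair 2.

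Matrix, adhesion and guidance genes changed in both directions. Among 22 matrix genes, Lama5, Reln, Hspg2 and Col4a1 rose and Thbs1 and Tnr fell. Among 26 integrin and adhesion genes, Mcam, Itga1 and Pcdh19 rose and Cdh13 fell. Among 44 axon guidance genes, Plxnd1, Dpysl3 and Epha5 rose and Crmp1, Ntn4, Robo2 and Plxna1 fell. Tgfb2 was the 1 riser among 13 mesenchymal transition genes, and none of 28 epithelial junction and keratin genes passed.

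The basement membrane gene Lama5 went from 31.2 ± 9.74 to 56.3 ± 20.8 CPM (SD, n = 4), by 0.83 ± 0.13 in log2 terms (SE, DESeq2 adjusted p of 3.96e-08). Mcam rose by 0.93 ± 0.15 (adjusted p of 6.99e-07), Cdh13 fell by 0.62 ± 0.12 (adjusted p of 6.92e-05) and Plxnd1 rose by 1.44 ± 0.29 (adjusted p of 9.3e-05). These genes and Itga1 passed without any single pair. Reln, Hspg2, Thbs1, Pcdh19 and Dpysl3 passed in 3 of the 4 fits that left out a pair, Col4a1, Epha5, Crmp1, Ntn4 and Tgfb2 in 2, and Tnr, Robo2 and Plxna1 in 1. Tnr and Plxna1 did not pass with total-count scaling. Reln and Col4a1 were higher in 3 pairs and lower in pair 3, where both had under 0.5 CPM, and Pcdh19 had no counts in pair 2. Adjusted over the list alone, DESeq2 gave 4 rising and 2 falling matrix genes, 5 and 3 adhesion genes, 4 and 6 guidance genes, and 1 and 0 mesenchymal genes. The paired edgeR test gave 4 and 2, 3 and 2, 3 and 1, and 1 and 0.

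Further lists covered metabolism, mitochondrial transcripts and the ribosome. Of 24 tested genes of the cholesterol list 5 fell, among them Dhcr7, Sc5d, Sqle and Tm7sf2, and 0 rose. Mitochondrially encoded transcripts fell (mt-Nd4, mt-Cytb, mt-Co1 and mt-Nd5, 4 of 11), while the ribosomal protein genes Rps4x, Rps20, Rps18 and Rps19 rose, 4 of 40. In the glycolysis and hypoxia list, Slc16a1, Hk1 and Eno1 fell and Aldoc rose. Cell-cycle genes were not called: none of 27 proliferation genes and none of 38 DNA replication and E2F target genes passed, although scaling by total counts gave 1 riser in the latter.

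Dhcr7 fell by 0.50 ± 0.09 in log2 terms (SE, DESeq2 adjusted p of 3.08e-05), in all 4 pairs and without any single pair, whereas the median of the cholesterol list was 0.12 in pair 3 and negative in the other pairs. Only 2 cholesterol genes fell with total-count scaling, and 2 were called without replicate 1 or without replicate 2. Sc5d passed in 0 and Sqle and Tm7sf2 in 1 of the 4 fits that left out a pair. Aldoc passed in 4, mt-Nd4 and Slc16a1 in 3, mt-Cytb, mt-Co1, mt-Nd5 and Hk1 in 1, and Eno1 in 0 and not with total-count scaling. The share of counts from mitochondrially encoded genes was lower with Nfib in each pair. It went from 3.86% to 3.46%, from 4.81% to 3.48%, from 3.84% to 3.63% and from 2.55% to 2.20% in pairs 1 to 4. Ribosomal protein changes were small, between 0.17 and 0.21 for the 4 genes, and with total-count scaling 8 members rose. Without replicate 1, 3 or 4 none of the list passed, and without replicate 2 it was 1. Such genes have near-identical copies in the genome. Adjusted over the list alone, DESeq2 gave 7 falling cholesterol genes, 7 falling mitochondrial genes, 6 rising ribosomal protein genes, and 1 rising with 7 falling glycolysis genes. For the paired edgeR test these counts were 4, 6, 0, and 1 with 2. In that test all 24 cholesterol and all 11 mitochondrial genes had negative log2 fold changes, and all 40 ribosomal protein genes positive ones. Members of a list can vary together, so these signs are not independent.

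Of the remaining lists, single members passed in several. Slc1a2 rose and Aldh1l1 fell among 12 glial genes, and Fgfr1 rose and Kit fell among 27 signalling regulators. Xbp1 (1 of 29 stress response genes), Dusp1 (1 of 19 immediate early genes) and Mybbp1a (1 of 31 ribosome biogenesis genes) rose. All 31 ribosome biogenesis genes had a positive log2 fold change in the paired edgeR test, with a median of 0.12. Slc1a2 and Fgfr1 passed in 3 of the 4 fits that left out a pair, Kit and Xbp1 in 2, and Aldh1l1, Dusp1 and Mybbp1a in 0. With total-count scaling Aldh1l1 did not pass, and 2 stress response and 5 ribosome biogenesis genes rose. None of 8 MYC family, 20 polycomb and DNA methylation, 23 interferon response and 13 heat shock genes passed. Adjusted over the list alone, DESeq2 gave 2 rising and 1 falling glial genes, 1 rising and 2 falling signalling genes, 1 rising stress response gene, 2 rising and 1 falling immediate early genes, and 2 rising ribosome biogenesis genes. The paired edgeR test gave 1 rising glial gene, 1 rising immediate early gene and 0 in the other lists of this group. For the MYC, polycomb, interferon, heat shock, epithelial, proliferation and E2F lists both tests gave 0.

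Few markers of other cell types had enough counts to be tested. Of 8 lung alveolar and airway markers, whose median log2 ratio was positive in all 4 pairs, Aqp5 rose, and the most abundant, Abca3 (94.7 ± 17.9 against 95.3 ± 17.7 CPM, SD, n = 4) and Tppp3 (5.47 ± 2.59 against 5.30 ± 1.31 CPM), had log2 fold changes of 0.00064 and 0.0089 whose sign depended on the test. The leukocyte markers had 2 tested members, Coro1a, which fell by 0.47 ± 0.14 (SE, DESeq2 adjusted p of 0.0302), passed in 1 of the 4 fits that left out a pair and did not pass with total-count scaling (-0.43), and Cd68, at 1.65 ± 0.461 CPM in empty vector libraries. Of 6 fibroblast and endothelial markers none passed, and Vwf (276 ± 280 CPM in empty vector and 260 ± 257 CPM in Nfib libraries) and Fbln1 (16.2 ± 15.7 against 18.2 ± 15.1 CPM) were the most abundant. DESeq2 gave, adjusted over the list alone, 2 rising lung markers, 1 falling leukocyte marker and 0 fibroblast and endothelial markers, and the paired edgeR test gave 3, 1 and 0.

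As sets, 8 of 28 lists passed camera with the preset correlation and without the block at a Benjamini-Hochberg adjusted p under 0.05. The NFI family, Notch, ribosomal protein, ribosome biogenesis and lung lists were up and the neuroendocrine, cholesterol and mitochondrially encoded lists down. With the block 12 passed: the same 8, the stress response list up, and the neuronal, interferon and glycolysis lists down. None held with an estimated correlation, where the smallest adjusted p was 0.27 without and 0.53 with the block, and fry, which asks whether a set's genes move one way, passed 0 lists without the block and 1, the NFI family, with it (adjusted p of 0.00945). The NFI list contains Nfib, the introduced gene, so its passes by camera and fry were to a large part set by the design. A form of fry for genes moving in either direction, outside the fixed plan, was also run with the block. Its adjusted p was 0.000539, 0.00605 and 0.00915 for the adhesion, matrix and guidance lists. For the proliferation and epithelial lists it was 0.796 and 0.367. That form asks whether any members change, and not whether a list differs from other genes.

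**Figure D3:**
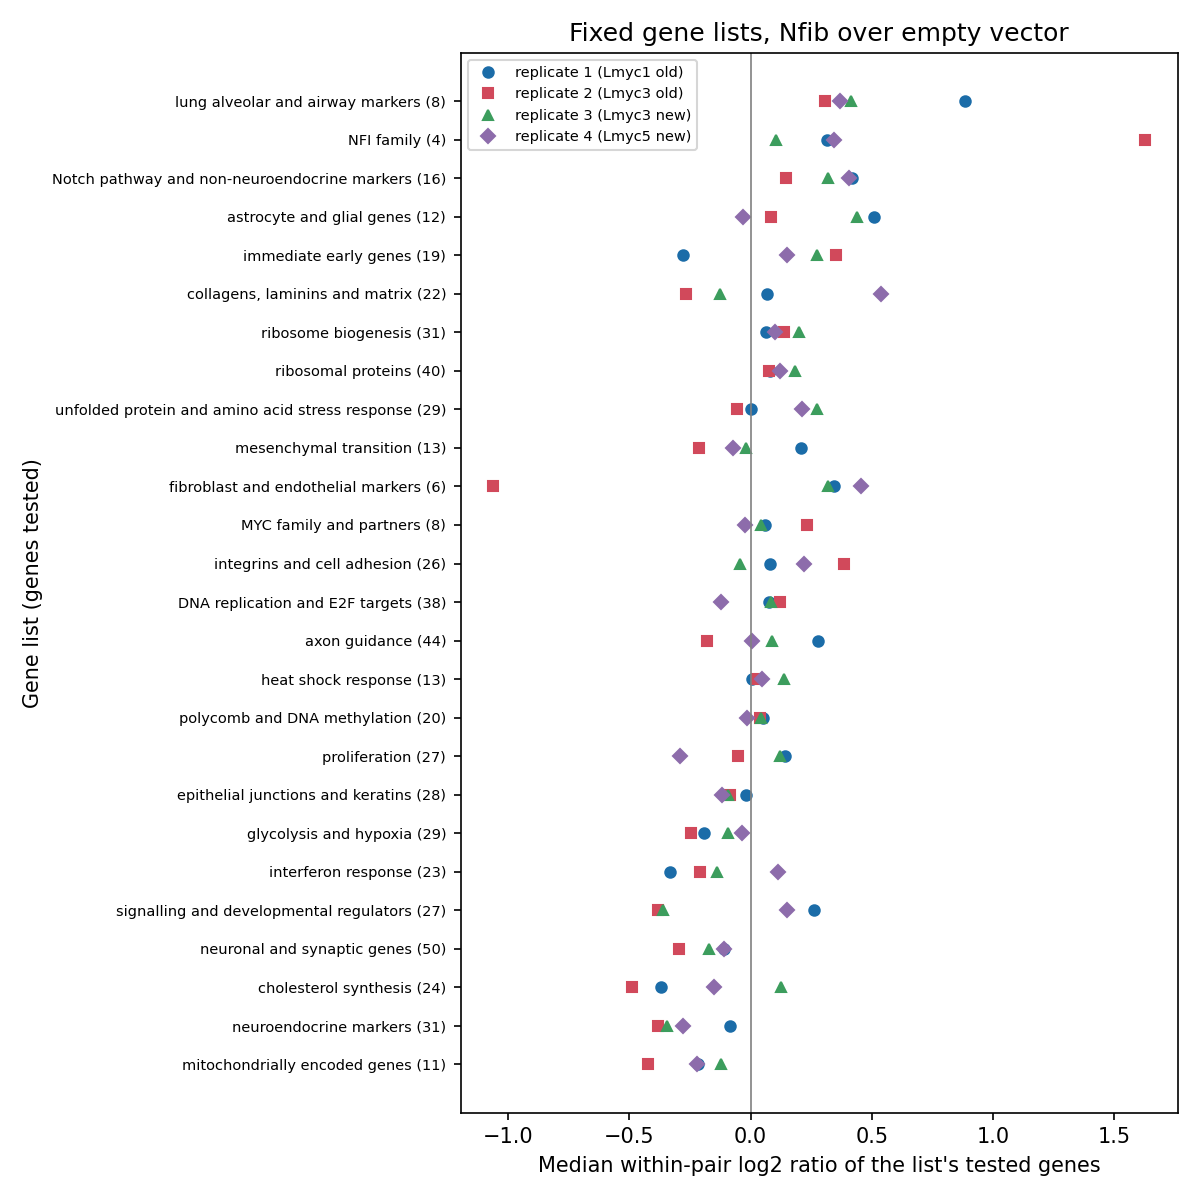
Median within-pair log2 ratio (Nfib over empty vector) of the tested genes of each fixed list reported here, with 1 symbol per pair and the number of genes tested in brackets. The neuroendocrine, neuronal, mitochondrially encoded, glycolysis and epithelial lists have negative medians in all 4 pairs. The Notch, NFI, lung, heat shock and both ribosomal lists have positive ones, and the cholesterol list is negative in 3 of 4.

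The descriptions divide the pairs into old and new, and a further comparison asked whether the Nfib effect differed between them. No gene was shown to differ by the edgeR interaction test with the block, which called 0 genes, with 405 at an unadjusted p under 0.05 against 669 by chance. DESeq2 with the same design called 7 genes, Anpep, Slc35f1, Kcnip1, Ttc7b, Fat3, Dusp4 and Chrm2, named here after their values were seen. It had 248 genes at an unadjusted p under 0.05, also fewer than the 669 by chance. Across all genes the within-pair effects were alike only to a degree. Their Pearson correlations between pairs ran from 0.16 to 0.41, across genes that are not independent replicates, and were 0.16 for the old pairs and 0.27 for the new pairs.

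The cell lines differed more from each other than the arms did. Log2 CPM correlated at 0.973 to 0.985 within pairs and at 0.810 to 0.887 between empty vector libraries, where between 2875 and 4138 of 13380 genes differed by more than 2-fold. The largest number was between replicates 2 and 3, both labelled Lmyc3. In pair 2 genes on chromosome 11 were higher in the Nfib library as a group, with a median log2 ratio of 0.26 over 1029 genes of at least 1 CPM, of which 79.5% were positive. Chromosome 3 was lower in the same pair, with a median of -0.13 over 590 genes and 35.3% positive. All other chromosome medians lay between -0.04 and 0.07 in every pair. Chromosome 11 held 31 of the genes that rose and 9 of those that fell in the paired test. Of the named genes, the risers Mgat4b, Xbp1, Aldoc, Mybbp1a and Myl4 and the fallers Upp1, Nefh and Dlg4 lie on chromosome 11, and Gria2, Slc16a1, St6galnac5, Notch2, Hey1 and Kcnd3 on chromosome 3. Their log2 ratios in pair 2 include these shifts.

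**Figure D4:**
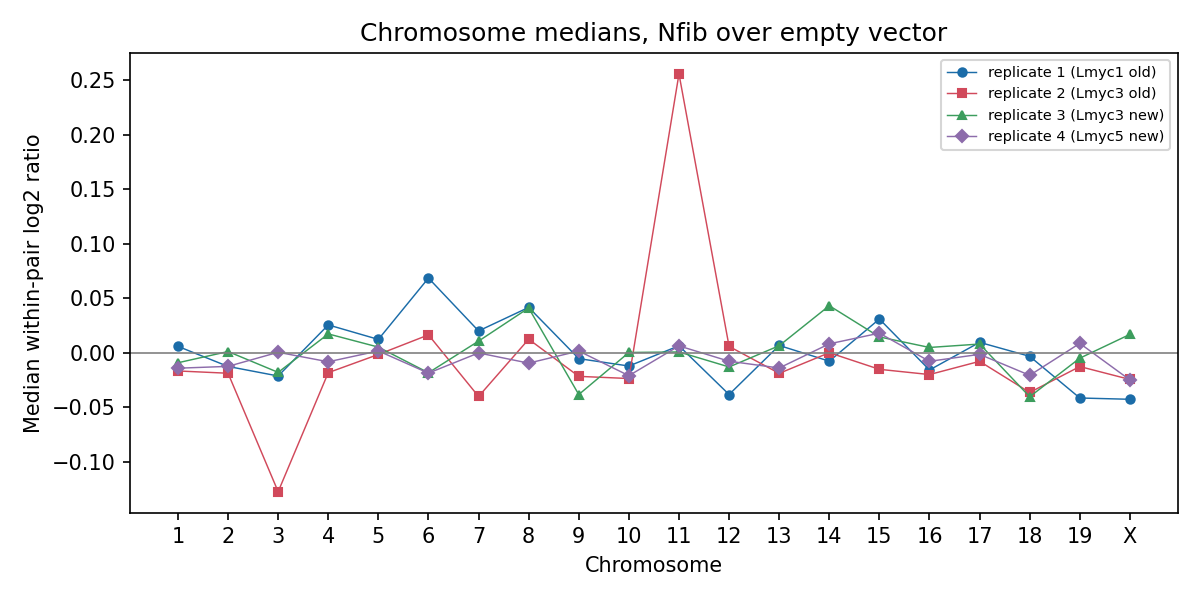
Median within-pair log2 ratio (Nfib over empty vector) of genes with a mean of at least 1 CPM, by chromosome, with 1 line per pair. Chromosome 11 stands at 0.26 in pair 2 and at 0.01, 0.00 and 0.01 in pairs 1, 3 and 4.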

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

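The splits of the edgeR results, the spread of the lines, and all tests on the neuroendocrine list were chosen or altered after results were seen, and the test of held-out pairs and the splits of the DESeq2 and list results before.

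Mycl was far higher in replicate 2 than in the other replicates of both groups. With empty vector it stood at 463 CPM in replicate 2 against 118 to 156 CPM in the others, and with Nfib at 1128 CPM against 166 to 256 CPM. The mitochondrial share of the Nfib library of replicate 4, at 2.20%, lay below the 3.46% to 3.63% of the other Nfib libraries. Pair 2 also stood apart in the median log2 ratio of the NFI family (1.63 against 0.10 to 0.35, where Nfix and Nfic add to Nfib) and of the fibroblast and endothelial markers (-1.06 against 0.32 to 0.45). Pair 4 did so for the polycomb list (-0.0151 against 0.0388 to 0.0497). In all, 6 of 84 groups of 4 values had such a distant member, and chance gives about 1 in 20.

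By the DESeq2 interaction test 7 genes passed for a different Nfib effect in old and new pairs, and none of them passed by edgeR. The DESeq2 test had 248 genes at an unadjusted p under 0.05, where 669 would arise by chance. Old pairs are of Lmyc1 and Lmyc3 and new pairs of Lmyc3 and Lmyc5, so old or new cannot be fully told apart from line. The label Lmyc3 is on both sides, but with 1 pair each, and whether both pairs are of one line is uncertain. Anpep (Benjamini-Hochberg adjusted p of 0.000395) had log2 ratios of 6.44 and 3.53 in the old pairs and 0.46 and 0.77 in the new pairs, whose empty vector libraries already held 36.8 and 47.1 CPM against 0.170 and 0.473. Slc35f1 followed with an adjusted p of 0.000409 from the DESeq2 interaction, but the old pairs went opposite ways (0.61 and -1.64) and the libraries of pairs 1 and 3 held at most 0.0436 CPM, which leaves pair 2 against pair 4 (1.11). The adjusted p was 0.0121 for each of Kcnip1, Ttc7b and Fat3. In Kcnip1 the ratios were 1.04 and 4.34 in old and -0.96 and -0.49 in new pairs, in Ttc7b -0.34 and 0.02 against -1.87 and -1.48, in Fat3 -0.09 and -0.86 against 1.10 and 1.55, and in Dusp4 -0.59 and 0.25 against 1.28 and 1.48. The DESeq2 adjusted p was 0.0296 for Dusp4 and 0.0443 for Chrm2, which fell in all 4 pairs, by more in the old ones (-1.87 and -1.96) than in the new (-0.76 and -0.82).

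The paired DESeq2 test called 543 genes where edgeR called 0. Noise of the DESeq2 test as the whole source of these calls was tested on held-out pairs. Genes called from 3 pairs moved in the called direction in the left-out pair in 84.5%, 78.6%, 86.6% and 81.8% of cases for pairs 1 to 4, against 59.4% to 62.9% over all genes, which argues against it. Part of the calls may still be false, as 23.4% were in the simulated data. That share depends on the number of genes changed there and cannot be carried over to the 543. The SD among the empty vector libraries was 2.19 times that of the within-pair ratios, in line with line differences hiding the effect without the block.

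For edgeR without the block the count of genes is 0, which each of the 35 splits reaches by necessity, so this test says nothing about chance. The highest other split called 1646 genes. It set pairs 1 and 3 against pairs 2 and 4, the split of old against new pairs called 878, and the split of pairs 1 and 4 against 2 and 3, the only one to keep the Lmyc3 label on one side, called 46. Only these 3 splits called genes, and all of them keep the arms of each pair together, while the 7 others that part every pair called 0. With the block the 8 swaps within pairs are too few for a share under 0.05. EdgeR called 0 genes in all 8, again a test that could not fail, and for DESeq2 only 1 of 8, the real one, reached 543, with 51 as the highest of the others. For camera without the block, 11 of 35 splits gave at least the 8 lists of the real split, with up to 12 in the others, so chance could not be excluded. With the block 2 of 8 gave at least 12 lists, with a highest other of 13, and the swaps are again too few for a share under 0.05.

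The median of the neuroendocrine list was lower in the Nfib library of each pair, but 7 of its 31 members passed by DESeq2, and the list did not pass camera with an estimated correlation (adjusted p of 0.270 without and 0.532 with the block) or fry with the block (0.191). A fall carried by one pair is argued against by the median log2 ratio, which stayed at or below -0.23 without each pair in turn. Deeper sequencing of one arm is argued against because the median was negative in all 4 pairs (highest -0.0847), of which pairs 2 and 4 had the deeper Nfib library. The tests of a smaller share of neuroendocrine cells assumed that it lowers all markers alike. That holds only if the remaining cells express none of the markers, which was not measured. A first test of a smaller share, on the interquartile range of the members' log2 fold changes, gave 0.384. This was over its bound of 0.2, which by its rule would have counted against the explanation. It was replaced after that value was seen, because sampling error alone (median SE of 0.164) can give a range over that bound, and whether it can give the range found was not tested. The order of the 31 members was shared between pairs, with a mean Spearman correlation of 0.2003 (one-sided permutation p of 0.00706), close to the 0.225 over all genes. The bound for this second test was a mean over 0.2, which the value passed by less than its SE of 0.0723. The condition that it pass by more than its spread was added after the value was seen. Without it the rule would have counted the explanation as argued against, under the same unchecked assumption. Whatever the bound, a shared order cannot decide, since markers that other cells express unequally would also fall in a shared order. A smaller share thus cannot be told apart from an effect of Nfib on expression in each cell, which stays open as a hypothesis.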

How the results depend on the processing

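The alternatives of the paired DESeq2 counts, the DESeq2 fits of named genes without 1 replicate and the bias-adjusted edgeR fit were chosen after the results were seen, the others before. The edgeR count of 0 higher and 0 lower genes stayed at 0 with the replicate block, the line block, the summed Lmyc3 pairs, old or new as a covariate, DESeq2 size factors, total counts, the CPM filter, Nfib left out and each replicate or library left out. Other tools moved it. The pair as a random effect in voom gave 1 higher gene, DESeq2 without the block 3, voom with the block 3, and DESeq2 with the block 249 higher and 294 lower. With the block, edgeR gave 26 higher and 12 lower genes without a low-count filter, 11 and 4 at an adjusted p under 0.1, and 30 and 14 in the bias-adjusted fit. The cause was not tested.

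The interaction count of 0 became 7 with DESeq2 and stayed at 0 elsewhere. Of the 8 lists passing camera, 0 passed with an estimated correlation, without or with the replicate block, and 1 with fry and the block, the NFI family, which contains Nfib itself. Leaving out a replicate gave between 8 and 14 lists over both forms of the test, and the block alone gave 12.

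The paired DESeq2 counts of 249 higher and 294 lower genes became 134 and 142 at an adjusted p under 0.01. They ranged from 108 to 176 higher and from 89 to 213 lower genes without 1 replicate, with fewer libraries in the fit. TMM factors, total counts, other filters and the summed Lmyc3 pairs kept both within 1.5 times, but of the 543 genes only 351 were also called with the summed pairs. No gene of the 543 changed sign in any of these fits, which reuse the same libraries. Since 521 of the 543 moved the same way in all 4 pairs, this could hardly have come out otherwise. Of the 543, 201 to 273 were called without 1 replicate. Without 1 replicate, 3 to 7 neuroendocrine, 2 to 5 cholesterol and 0 to 1 ribosomal protein genes were called, not always the same ones. Of the 7, 5 and 4 called with all pairs, 2 to 4, 2 to 3 and 0 to 1 stayed called.

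Among 110 named genes, 100 were called by the paired DESeq2 test. All 100 lost their call with edgeR, with or without the block, as its count of 0 requires. With DESeq2 without the block 98 lost it. Signs turned in 3 genes that passed nowhere. Nfia ranged from -0.37 to 0.0066 without 1 replicate. Abca3 gave -0.000336 by DESeq2 without the block and -0.000182 with DESeq2 size factors, and -0.0398 to 0.0636 without 1 replicate. Tppp3 gave -0.0475 by edgeR without the block, -0.0577 by DESeq2 without the block, -0.0558 with DESeq2 size factors, -0.0305 with total counts and -0.0511 without a filter, and -0.17 to 0.24 without 1 replicate. Depth limits genes near the floor of 3 counts per library, among them several of the largest rises.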

Other observations

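The correlation of regional profiles was chosen before its result was seen, and the SD of regional differences and the test of sex-linked genes after.

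Replicates 2 and 3 carry the same line label, Lmyc3, yet their empty vector libraries differed in more genes by over 2-fold (4138) than those of any other pair of replicates. Different animals by sex are argued against by Ddx3y, at 69.3 CPM or more in all 4 Lmyc3 libraries, and Xist, at 1.81 CPM or less. Lmyc1 and Lmyc5 libraries had 1400 CPM or more of Xist and at most 1 count of Ddx3y. If both came from the same tumor line, shared copy number changes should make their expression profiles along the chromosomes alike. Over 252 windows of 10 Mb, the profiles of the Lmyc3 controls correlated at -0.40, below the highest of the other pairs of controls (-0.04), while the arms of the same replicate correlated at 0.901 to 0.946. Profiles were centred over the 4 libraries of an arm, which alone gives about -0.333 between unrelated profiles of equal spread, so -0.40 shows a lack of likeness and not opposed profiles. The SD of the differences between windows, from which the centring largely cancels, was 0.351 for the Lmyc3 controls, within the 0.282 to 0.431 of the other pairs. The values are consistent with separate male tumor lines behind the label, and divergence of one line between old and new cultures stays open, since a line can lose a shared profile. The line block, which assumes that both pairs share a baseline, rests on the label.

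In pair 2 the median log2 ratio was 0.08 to 0.43 in each of the 13 windows of chromosome 11. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty all had more CPM in the Nfib library of that pair (165 against 90.1 for Ddx3y). In pair 1 Xist went from 2508 to 1400 CPM. These values enter the within-pair ratios and were not corrected for.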
